A study of Homo sapiens with 28 samples.

How the data were processed

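CUT&RUN, in which an antibody directs a nuclease to the chromatin around its target, was applied to human CD14+ monocytes from buffy coats, per the labels. Targets were the transcription factor IRF1, the histone mark H3K27ac of active promoters and enhancers, and the histone mark H3K4me3 of active promoters. There were 28 libraries, 12 for IRF1 (4 treatments with 3 replicates each), 8 for H3K27ac and 8 for H3K4me3 (4 treatments with 2 replicates each). The treatments were resting, IL-10, LPS and IL-10 + LPS, each taken from the label of its sample. Cells were cultured overnight with 20 ng/ml M-CSF before treatment, per the labels' protocols. The dose and duration of LPS and IL-10 are not given in the sources used here, because the labels' treatment protocol names other stimuli. The labels do not say that replicates came from separate donors, so p-values measure only the spread between these samples that the removal described below left in.

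The 2 deposited tables, for IRF1 and H3K27ac, hold log2 CPM of reads in peaks, computed by the authors. Neither table states its unit. The log2 scale and the scaling to reads in peaks were read from the values, which are negative or fractional, hold no ties, and sum to between 901293 and 1140792 per library once 2 is raised to their power. Bowtie2 and MACS2 are named, with no version or role, per the submitters' processing notes, which also name the build GRCh38 (hg38). The deposited peak lists are merged over the libraries of a target and hold a chromosome, a start and an end, with no score. For H3K4me3 only this list was used here. Within each table the mean over the 4 treatments was identical for every column number at every peak, to within 5.9e-14 for IRF1 and 1.6e-14 for H3K27ac. A shift per column number and peak had thus been removed before deposit. The column heads write D before the number where the labels write Rep, and this D was not taken to name donors. Column numbers were taken to be the replicate numbers of the labels. Reads per library are not given, so the depth is unknown, and no counting interval is printed.

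The IRF1 table held 14959 peaks and that of H3K27ac held 61562, each in its merged list. Peaks on chromosome Y, the mitochondrion and unplaced contigs and around XIST were left out (20 and 111). Peaks with a mean under 1 on the linear scale were left out too, which left 14939 IRF1 and 61446 H3K27ac peaks. Each peak was tested with limma-trend (limma 3.58.1, R 4.3.3), fitted to all 4 treatments of a target, two-sided, with Benjamini-Hochberg adjustment over all tested peaks of a comparison. A peak was called at an adjusted p under 0.05. Comparisons were LPS against resting, IL-10 against resting, IL-10 + LPS against LPS, IL-10 + LPS against IL-10, and the interaction, the IL-10 change with LPS minus the IL-10 change without it. Standard errors (SE) are those of the fit. Spreads given as SD are between replicates, on the deposited values. They leave out replicate differences shared over the treatments, which the removal described above took out, and so understate the spread between replicates.

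The removal of the column-number shift takes degrees of freedom that a fit without a block still counts (8 against 6 for IRF1, 4 against 3 for H3K27ac). A fit with the replicate number as a block was therefore run for every comparison of peaks and every gene list. Its value is printed where a named call is lost or a total count changes by more than 1.5 times, and beside some other total counts and some list counts of IRF1. It was not run for some other results, among them the random lists, the sign shares and H3K27ac at IRF1 peaks raised by IL-10 or by LPS. The removal also forces same-numbered libraries to deviate in opposite directions, so the correlation of their deviations cannot show whether the numbers pair the samples. The pairing rests on that removal and on columns numbered alike over the treatments. The fits were tested on simulated data for LPS against resting, with 200 peaks changed in each of 5 runs. Of 14939 IRF1 peaks, the fit without a block recovered 0.294%, 18.5% and 78.2% of changes of 1, 2 and 4 on the log2 scale, and 15.8% of its calls were false. The block lowered these to 0%, 10.9% and 69.4%, with 5.36% false calls. Of 61446 H3K27ac peaks, the recovered shares were 18.5%, 71.5% and 99.1% without a block, with 4.86% false calls, and 24.1%, 79.1% and 99.7% with it, with 5.49%. Unchanged peaks had an unadjusted p under 0.05 in 9.22% (IRF1) and 9.11% (H3K27ac) of cases without the block, and in 5.05% and 4.96% with it. Random peak sets had a camera p under 0.05 in 1.4% (IRF1) and 1.2% (H3K27ac) of cases. Simulated peaks varied independently, so these rates do not cover lists with correlated peaks. The recovered shares depend on how many peaks change. As 5344 IRF1 peaks were called with LPS in the data, against 200 changed per run, they do not give the power in these data.

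Peaks were assigned to the protein-coding gene (RefSeq, GRCh38, 19970 genes) whose nearer end lay closest to the peak centre, within 100000 bp. The annotation used gives gene ends in place of transcription start sites, so distances are to the nearer gene end. Overlaps were counted with bedtools 2.31.1 at 1 bp or more. IRF1 peaks that overlap an H3K27ac or an H3K4me3 peak are called marked, and the others unmarked.

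Gene lists were written before the data were examined, as were the tests, the first set of alternatives and the rule for named genes. There were 13 lists with 515 symbols, of which 2 were not in the annotation: type I interferon-stimulated genes, interferon-gamma, GBP and antigen presentation genes, inflammatory cytokines and chemokines, NF-kB pathway and feedback genes, IL-10 and STAT3 response genes, co-stimulation, TLR and JAK-STAT receptor genes, monocyte and macrophage identity genes, glycolysis and hypoxia genes, lysosome, lipid and cholesterol genes, ribosomal protein genes, T and NK cell markers, B cell markers, and platelet, erythroid and neutrophil markers. Each list was tested with limma camera, which sets the peaks of a list against all other peaks, at a preset correlation of 0.01 and again with an estimated one. List p-values were adjusted over the 13 lists of a comparison. Named genes followed this rule: the 10 largest rises and the 10 largest falls among called peaks whose groups did not overlap, up to 4 genes per list with the smallest p, the 5 smallest p for the interaction and for IL-10 + LPS against IL-10, and 18 loci fixed in advance at their nearest peak within 5000 bp. Members of the rule were left out where space was short, and none was added.

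Alternatives covered the pseudocount, the filter, quantile normalization, a common median, the libraries in the fit, the replicate block, the intensity trend, a minimum change of 1 on the log2 scale, the distance to genes, the overlap, and leaving out each replicate. The share of LPS-raised peaks lowered by IL-10 was set beside the share of independent lists. The sign and size of the IL-10 change at those peaks were set beside 20 simulations with no IL-10 effect that share the LPS libraries, a check added after the data were seen. Lists were also set beside 10000 random lists of marked peaks matched on mean value, again chosen after the data were seen. Their peaks were drawn singly, so their ranges leave out the correlation between peaks of a list. Other computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Whole reads could not be recovered from the tables, so no count-based test was run. Motifs were not analysed here, because no genome sequence was used.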

Results

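Monocytes from human blood were left resting or treated with LPS, a bacterial activator of toll-like receptor 4, with the anti-inflammatory cytokine IL-10, or with both, to ask how IL-10 regulates LPS responses, per the series design. IRF1, an interferon-induced transcription factor, was mapped in 3 libraries per treatment and the active-chromatin mark H3K27ac in 2, and H3K4me3 was described from a merged peak list. Merged lists held 14939 IRF1, 61451 H3K27ac and 14224 H3K4me3 peaks, with median widths of 224, 1334 and 1685 bp. Of the H3K4me3 peaks 68.6% had their centre within 2000 bp of a gene end, against 12.2% of IRF1 and 20.2% of H3K27ac peaks. After the lists were shifted by 1 Mb these shares were 8.08%, 4.93% and 6.56%. H3K27ac peaks covered 48.8% of the IRF1 peaks and 94.2% of the H3K4me3 peaks, and 50.8% of IRF1 peaks (7590) overlapped at least 1 of the 2 marks. All values are log2 CPM of reads in peaks, the depth is unknown, and all coordinates are in GRCh38.

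LPS raised IRF1 signal near antiviral and antigen presentation genes. The IRF1 peak at ISG15, a ubiquitin-like antiviral protein (chromosome 1, 1012979 to 1013694), went from 6.60 ± 0.51 in resting cells to 9.78 ± 0.70 with LPS (SD, n = 3), a change of 3.17 ± 0.40 (SE, adjusted p = 4.08e-05, limma). At OAS3, an activator of RNase L, IRF1 rose by 3.10 ± 0.36 (adjusted p = 2.47e-05), and at the interferon-induced genes OASL, IFIT1 and IFIT3 by 3.21, 2.96 and 2.98. IRF1 near GBP5, a guanylate-binding protein that acts in inflammasome responses (chromosome 1, 89274230 to 89274887), rose by 3.87 ± 0.38 (adjusted p = 9.17e-06), and at GBP1 by 2.41 ± 0.46. The proteasome activator gene PSME2 gained 2.81, CD274, which encodes the inhibitory ligand PD-L1, gained 3.35, and IDO1, a tryptophan-degrading enzyme, gained 2.61. At the chemokine gene CXCL10 the rise was 2.09 ± 0.65 (adjusted p = 0.0183).

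Genes of inflammation and cell activation gained IRF1 signal as well. IRF1 rose by 4.52 ± 0.51 at C2, a complement component (adjusted p = 1.64e-05), and by 4.44 ± 0.63 near NLRP3, the inflammasome sensor (adjusted p = 0.000118). Near IL1RN, the interleukin-1 receptor antagonist, it rose by 3.25 ± 0.37 (adjusted p = 2.06e-05). Rises near IL12B, 55530 bp away, and at IL27, which encode cytokine subunits, were 3.10 and 2.34, and near PTGS2, the inducible cyclooxygenase, 2.66. Peaks near CD80, a ligand of CD28, and near CD48 gained 3.68 and 3.12, a peak 58885 bp from TLR4 gained 2.85, and 1 near HK2, a hexokinase that starts glycolysis, gained 3.90. IL1B gained 1.75 ± 0.51 (adjusted p = 0.013) and IL6 1.40 ± 0.47 (adjusted p = 0.0263, and 0.0835 with the replicate block). At CD40 the change of 1.59 ± 0.62 did not pass (adjusted p = 0.0503). Among the largest falls was that near CLDN18 (-4.93 ± 0.70), an epithelial claudin gene, and near the platelet integrin gene ITGB3 IRF1 fell by 3.82. Groups did not overlap at any peak named as changed, which the naming rule required of the largest rises and falls. They did not overlap at 5019 of the 5344 called peaks and at 7106 of all 14939 peaks. Chance gives this at 10% of peaks with 3 against 3 independent libraries. After the removal of the column-number shift the chance share is higher, and it was not computed.

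Among the gene lists, 64 of 112 IRF1 peaks at type I interferon-stimulated genes rose and 4 fell (67 and 4 adjusted over the list alone), and 41 of their 52 genes had only raised peaks, 1 only lowered, 3 both and 7 none (camera adjusted p = 1.91e-11). Of 110 peaks at interferon-gamma, GBP and antigen presentation genes 69 rose and 2 fell (74 and 2 adjusted over the list alone), with an adjusted p of 2.44e-13. At marked peaks, those over an H3K27ac or H3K4me3 peak, the medians of these lists were 1.88 and 1.89, against 1.34 and 1.41 for random lists of marked peaks matched on mean value. Inflammatory cytokines and chemokines rose at 25 of 55 peaks and fell at 1 (27 and 1 adjusted over the list alone, adjusted p = 1.13e-05). NF-kB pathway genes rose at 42 of 82 and fell at 2 (48 and 2 adjusted over the list alone, adjusted p = 7.28e-08). IL-10 and STAT3 response genes rose at 26 of 58 and fell at 1 (26 and 1 adjusted over the list alone, adjusted p = 3.41e-05), and co-stimulation, TLR and JAK-STAT receptor genes at 31 and 3 of 71 (34 and 3 adjusted over the list alone, adjusted p = 1.31e-06). Glycolysis genes rose at 12 of 24 (13 adjusted over the list alone, adjusted p = 0.000795). These 12 peaks lay at 3 of the 11 genes, and 8 genes had none. Lysosome, lipid and cholesterol genes, among them the cathepsin gene CTSZ (2.84), rose at 21 of 48 and fell at 1 (23 and 1 adjusted over the list alone, adjusted p = 0.000148). Monocyte identity genes, with CTSS (2.30), rose at 14 of 56 and fell at 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00504), with 9 raised under the replicate block. These 9 calls held with an estimated correlation. Against the random lists of marked peaks, type I and interferon-gamma genes lay at percentile 100, co-stimulation genes at 99.7 and NF-kB genes at 99.4. Inflammatory (93.1), lysosome (93.6), glycolysis (91.2), IL-10 and STAT3 response (85.7) and identity genes (6.11) lay within the range of most random lists, so their gain is not told apart from that of marked peaks at large. The 4 remaining lists did not pass: ribosomal protein genes (2 of 12 peaks rose, adjusted p = 0.454), T and NK cell markers (1 of 20, 0.889), B cell markers (2 of 7, 0.263) and platelet, erythroid and neutrophil markers (1 of 3 fell, 0.755, with a median of 0.73 but a mean of -0.63).

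In all, 5344 of 14939 IRF1 peaks changed with LPS, 2969 upward and 2375 downward, or 2067 and 1623 with the replicate block. Of the raised peaks 2815 were marked, and of the lowered ones 1914 were unmarked, so that the median change was 1.33 at marked and -0.97 at unmarked peaks. The split rests on the scaling: quantile normalization gave 1401 higher and 2155 lower, a common median 2167 and 2917, and a common median of the unmarked peaks, a scaling chosen after the data were seen, 5727 and 871. These brought the median of all peaks from 0.40 to 0.24, 0.10 and 1.31. Without LPS replicate 2 the count was 3531.

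**Figure D1:**
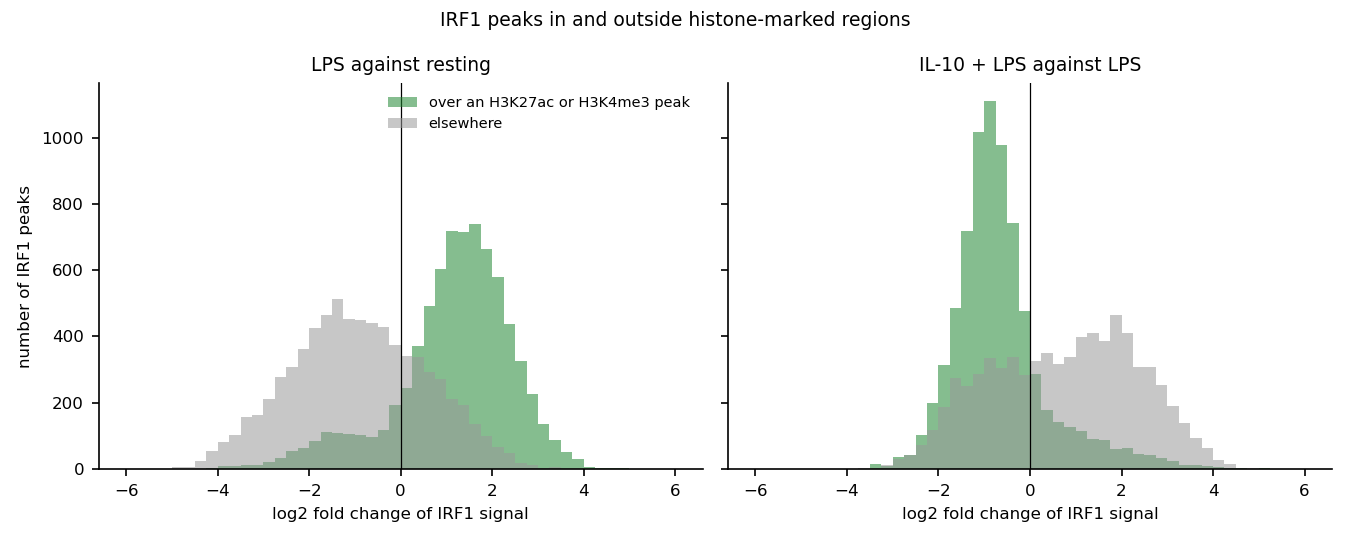
Histograms of the log2 fold change of IRF1 signal over 7590 peaks that overlap an H3K27ac or H3K4me3 peak (green) and 7349 elsewhere (grey), for LPS against resting and for IL-10 + LPS against LPS, with the number of peaks on the vertical axis. The medians lie at 1.33 and -0.97 on the left and at -0.81 and 0.86 on the right, on the scale of the deposited values.

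H3K27ac rose with LPS near feedback and signalling genes. Near TNC, an extracellular matrix glycoprotein (chromosome 9, 114999608 to 115000700), it went from 0.58 ± 0.20 to 5.86 ± 0.12 (SD, n = 2), a change of 5.28 ± 0.21 (SE, adjusted p = 4.8e-07). Peaks near SOCS3, an inhibitor of cytokine signalling, and TNFAIP3 (A20), which restrains NF-kB, rose by 4.75 ± 0.46 and 4.70 ± 0.37. The A20-binding protein gene TNIP1 and the NF-kB subunit gene NFKB1 gained 3.04 and 3.05, JAK1, a cytokine receptor kinase, gained 4.01, and CD80 3.32. At IDO1 the mark rose by 3.55 ± 0.35 (adjusted p = 6.25e-05), near the cytokine gene IL15 by 3.78, near CD274 by 2.63, at IL27 by 2.56, and near PFKFB3, a regulator of glycolysis, by 3.66. The chemokine genes CCL3 and CCL5 gained 3.25 and 2.86. Interferon-stimulated genes followed with ISG15 at 1.96 ± 0.19 (adjusted p = 5.18e-05), GBP5 at 1.97 ± 0.17, HERC6 at 2.18, ISG20 at 2.08, IFIT3 at 1.45 and GBP1 at 0.96. IL6 rose by 1.88, CD40 by 1.70, IL1B by 1.12, the peak nearest the IRF1 gene by 0.94 and TNF by 0.62 ± 0.18 (adjusted p = 0.0261). CXCL10 (1.27 ± 0.47, adjusted p = 0.072, and 0.0374 with the replicate block), NFKBIA (0.33, adjusted p = 0.199), BCL3 (0.56, adjusted p = 0.142) and IRF8 (-0.03, adjusted p = 0.899) did not pass. Falls included HPGDS, a prostaglandin D synthase (-3.44 ± 0.50), and the lipid receptor gene PPARG (-2.03). Groups of 2 libraries did not overlap at any of the 14561 called peaks, so their lack of overlap at named peaks adds no support. Over all 61446 peaks, 39857 had groups that did not overlap. Chance gives this in 1 of 3 splits of independent libraries, and more often after the column-number removal.

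By list, NF-kB pathway and feedback genes gained H3K27ac at 128 of 295 peaks and lost it at 13 (146 and 21 adjusted over the list alone, camera adjusted p = 2.38e-17, and 0.0418 with an estimated correlation). IL-10 and STAT3 response genes gained it at 107 of 332 and lost it at 41 (121 and 49 adjusted over the list alone, adjusted p = 5.52e-07, held with an estimated correlation). Type I interferon-stimulated genes rose at 87 of 210 and fell at 6 (100 and 9 adjusted over the list alone, adjusted p = 6.44e-13), which was lost at adjusted p = 0.382 with an estimated correlation. Interferon-gamma genes rose at 73 of 203 and fell at 26 (82 and 31 adjusted over the list alone, adjusted p = 5.52e-07), and inflammatory cytokines and chemokines at 62 and 20 of 179 (64 and 25 adjusted over the list alone, adjusted p = 5.93e-05). Both were lost at adjusted p = 0.382 with an estimated correlation. Co-stimulation genes rose at 64 of 254 and fell at 27 (71 and 30 adjusted over the list alone, adjusted p = 0.000389, lost at adjusted p = 0.456 with an estimated correlation). Glycolysis genes rose at 38 of 157 and fell at 8 (39 and 11 adjusted over the list alone, adjusted p = 0.000639, lost at adjusted p = 0.496 with an estimated correlation). T and NK cell markers fell at 32 of 74 and rose at 7 (35 and 10 adjusted over the list alone), with GNLY, CD28 and CD3E at -1.47, -1.58 and -1.23 (adjusted p = 0.00466, lost at adjusted p = 0.496 with an estimated correlation). Monocyte identity genes went both ways (47 rose and 57 fell of 289, adjusted p = 0.696, with a negative median beside an upward test), as did lysosome genes (17 and 36 of 200, 0.173), B cell markers (5 and 5 of 29, 0.994), platelet, erythroid and neutrophil markers (3 and 7 of 42, 0.382) and ribosomal protein genes (2 and 5 of 95, 0.862). In all, 14561 of 61446 H3K27ac peaks changed, 7087 upward and 7474 downward, but 7981 and 7272 with a common median and 6289 and 5534 with the replicate block. Without resting replicate 2 the count was 8503 (5372 and 3131), and without LPS replicate 2 it was 7943 (4652 and 3291).

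IL-10 alone raised H3K27ac at genes of its own signalling pathway. The mark rose by 2.82 ± 0.21 near SOCS3 (chromosome 17, 78351439 to 78354611, from 3.63 ± 0.39 to 6.46 ± 0.12, SD, n = 2, adjusted p = 0.000213). It rose by 2.16 ± 0.15 at SBNO2, a corepressor downstream of IL-10 (adjusted p = 0.000132), by 2.21 ± 0.18 near the kinase gene PIM1 and by 1.77 at the kinase gene JAK3. The inhibitory receptor genes LILRB2 and LILRB1 gained 2.73 ± 0.17 and 2.07, CDCP1, a surface glycoprotein, gained 3.31 ± 0.19 (adjusted p = 7.29e-05), and CD47, which signals against phagocytosis, gained 2.92. Near CD274 it rose by 1.70, near CXCL1 by 1.74, near TNIP3 by 2.15, near CD48 by 1.90, near IL7R by 1.70 and near CTSL, a lysosomal protease gene, by 1.22. Falls were smaller, with the ribosomal protein gene RPL3 at -1.70 ± 0.19, the NOD-pathway kinase gene RIPK2 at -1.30 and the dendritic cell activation marker gene CD83 at -0.86. None of the 17 H3K27ac peaks at the fixed loci passed. SOCS3 came closest (1.61 ± 0.39, adjusted p = 0.0516, and 0.000106 with the replicate block), while ISG15 (-0.10), GBP5 (0.15), TNF (-0.11) and IL1B (0.14) stood near their resting levels. Groups did not overlap at any of the 1792 called peaks, so their lack of overlap at named peaks adds no support. Over all 61446 peaks, 24163 had groups that did not overlap. Chance gives this in 1 of 3 splits of independent libraries, and more often after the column-number removal.

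Of the lists, IL-10 and STAT3 response genes rose at 40 of 332 H3K27ac peaks and fell at 1 (69 and 1 adjusted over the list alone), with 15 of 39 genes raised, 1 both and 23 none (adjusted p = 2.46e-09, held with an estimated correlation). Type I interferon-stimulated genes rose at 11 of 210 and fell at 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00476), among them TNFSF10 (1.29), IRF9 (0.97), IFI16 (0.93) and IFITM3 (1.05), and NF-kB genes rose at 12 of 295 and fell at 1 (16 and 2 adjusted over the list alone, adjusted p = 0.0212). Glycolysis genes rose at 11 of 157 (12 adjusted over the list alone, adjusted p = 0.00476), all of them near PFKFB3 (2.14 ± 0.19). These 3 calls were lost at adjusted p = 0.756 with an estimated correlation. Ribosomal protein genes fell at 3 of 95, all near RPL3 (3 adjusted over the list alone, adjusted p = 9.02e-05, lost at adjusted p = 0.514 with an estimated correlation). The other lists did not pass: interferon-gamma genes (7 of 203 rose, adjusted p = 0.166), inflammatory genes (8 of 179, 0.166), co-stimulation genes (6 rose and 4 fell of 254, 0.625), identity genes (9 and 2 of 289, 0.308), lysosome genes (7 and 2 of 200, 0.761), T and NK markers (2 of 74 fell, 0.0781), B cell markers (3 of 29 rose, 0.202) and platelet, erythroid and neutrophil markers (2 of 42 rose, 0.166). In all, 1263 H3K27ac peaks rose and 529 fell, or 838 and 619 with a common median. The count of 1792 became 1024 without resting replicate 2 and 1075 without IL-10 replicate 1.

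Few IRF1 peaks were called with IL-10 alone, a comparison whose power was not simulated. The fit without a block called 83 peaks higher and 42 lower, and limma with the replicate block called 0, beside 1853 peaks with an unadjusted p under 0.05 (2809 without it). Of the 83 raised peaks 64 were among those raised by LPS, against 16.5 for independent lists, and the covariance of the IL-10 and LPS changes was 0.932, against 0.395 in simulations where they only share the resting libraries. Examples were NLRP3 (3.66 ± 0.63, adjusted p = 0.0336, and 0.139 with the replicate block), the fungal receptor gene CLEC7A (2.40 ± 0.48, adjusted p = 0.0347, and 0.159 with the block) and the antiviral gene PARP14 (-2.67 ± 0.59, adjusted p = 0.041, and 0.17 with the block). No list passed (adjusted p from 0.0922 for ribosomal protein genes to 0.844 for platelet, erythroid and neutrophil markers), and that for type I interferon-stimulated genes was 0.199. Quantile normalization gave 235 higher and 249 lower and a common median 52 and 69, with a median of all peaks of 0.11 as deposited and -0.02 with the latter. The count of 125 became 20, 11 and 0 without resting replicates 1, 2 and 3, and 0, 1 and 0 without IL-10 replicates 1, 2 and 3.

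IL-10 lowered IRF1 signal near antiviral genes of LPS-treated cells. At RSAD2, the antiviral enzyme viperin (chromosome 2, 6865402 to 6866276), IRF1 went from 8.37 ± 0.29 with LPS to 6.11 ± 1.16 with IL-10 + LPS (SD, n = 3), a change of -2.27 ± 0.51 (SE, adjusted p = 0.00925). At OAS2 and TRIM22, both antiviral, the changes were -2.51 ± 0.59 and -1.78 ± 0.42, and at PML, which organises nuclear bodies, -3.63 ± 1.09 (adjusted p = 0.0303). Near ATF3, a stress-induced repressor, IRF1 fell by 3.32 ± 0.74 (adjusted p = 0.00853), near PFKFB3 by 2.63 ± 0.48 (adjusted p = 0.00428), and 6209 bp from the IRF1 gene by 2.28 ± 0.57 (adjusted p = 0.0139). Peaks near the lysosomal protease genes CTSB and CTSZ fell by 2.01 and 3.12. Their groups did not overlap, which the naming rule required of the largest changes. Groups did not overlap at 2358 of the 2440 called IRF1 peaks and at 5888 of all 14939 peaks. Chance gives this at 10% of peaks with independent libraries, and at more after the column-number removal. All calls named above in this comparison held with the replicate block. With the block after quantile normalization only that near PFKFB3 held, and quantile normalization alone lost those at TRIM22 and PML. Calls lost with the block were IDO1 (-1.20 ± 0.35, adjusted p = 0.0264, and 0.0924 with the block), IL6 (-1.62 ± 0.47, adjusted p = 0.0263, and 0.0926 with the block), GBP5 (-1.65 ± 0.52, adjusted p = 0.0371, and 0.114 with the block), and IL27 (-1.88 ± 0.49, adjusted p = 0.0171, and 0.0807 with the block). ISG15 (-1.15 ± 0.40, adjusted p = 0.0522), IL1B (-1.48, 0.0519), IFIT3 (-0.74, 0.195) and CXCL10 (-1.13, 0.213) did not pass. An upward change was called near LPL, a lipase gene (3.64 ± 0.72, from 1.08 ± 0.41 to 4.72 ± 0.71).

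Type I interferon-stimulated genes lost IRF1 at 19 of 112 peaks and gained it at 2 (20 and 2 adjusted over the list alone), with 31 of 52 genes showing neither (camera adjusted p = 7.32e-07). With the replicate block 4 peaks of this list fell. Interferon-gamma genes fell at 13 of 110 and rose at 2 (13 and 2 adjusted over the list alone, adjusted p = 3.12e-06), and inflammatory cytokines and chemokines fell at 7 of 55 (4 adjusted over the list alone, adjusted p = 3.86e-05). NF-kB genes fell at 6 of 82 (3 adjusted over the list alone, adjusted p = 0.000148), IL-10 and STAT3 response genes at 3 of 58 (1 adjusted over the list alone, adjusted p = 0.00078), co-stimulation genes at 6 of 71 with 1 raised (0 adjusted over the list alone, adjusted p = 7.82e-05) and identity genes at 3 of 56 (0 adjusted over the list alone, adjusted p = 0.0084). Lysosome genes fell at 4 of 48 and rose at 2 (2 and 2 adjusted over the list alone, adjusted p = 0.00499, lost at adjusted p = 0.0651 with an estimated correlation). Glycolysis genes fell at 1 of 24 and rose at 1 (1 and 1 adjusted over the list alone, adjusted p = 0.0299, lost at adjusted p = 0.0778 with an estimated correlation). The other 7 calls held. With the replicate block 2 interferon-gamma peaks fell and 2 rose, falls numbered 2 for NF-kB, 2 for lysosome, 1 for glycolysis and 1 for IL-10 and STAT3 response genes, and 0 inflammatory, co-stimulation and identity peaks fell (limma). Against random lists of marked peaks, inflammatory (percentile 0.01), type I (0.03), co-stimulation (0.05) and interferon-gamma genes (0.65) fell more. NF-kB (12.3), IL-10 and STAT3 response (38), identity (87.3), glycolysis (9.56) and lysosome genes (9.64) lay within the range of most random lists. The random lists were not matched on the LPS change, which shares the LPS libraries. For that change type I and interferon-gamma genes lay at percentile 100, co-stimulation genes at 99.7 and inflammatory genes at 93.1. Their percentiles for IL-10 thus do not show a fall beyond that of peaks with a like LPS rise. Ribosomal protein genes (adjusted p = 0.831), T and NK markers (0.89, with a median of -0.36 but a mean of 0.06), B cell markers (0.353) and platelet, erythroid and neutrophil markers (0.833, with a median of -0.03 but a mean of 0.37) did not pass.

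Over all IRF1 peaks, 1853 rose and 587 fell, or 762 and 91 with the replicate block. Of the raised peaks 1490 were unmarked, and of the lowered ones 463 were marked. Quantile normalization gave 1048 and 163, and a common median of the unmarked peaks, chosen after the data were seen, 852 and 4128, with medians of all peaks of -0.27 and -1.17 in place of -0.39. The count of 2440 became 1010 without LPS replicate 2, 1261 without LPS replicate 3, 1214 without IL-10 + LPS replicate 2 and 1379 without IL-10 + LPS replicate 3.

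**Figure D2:**
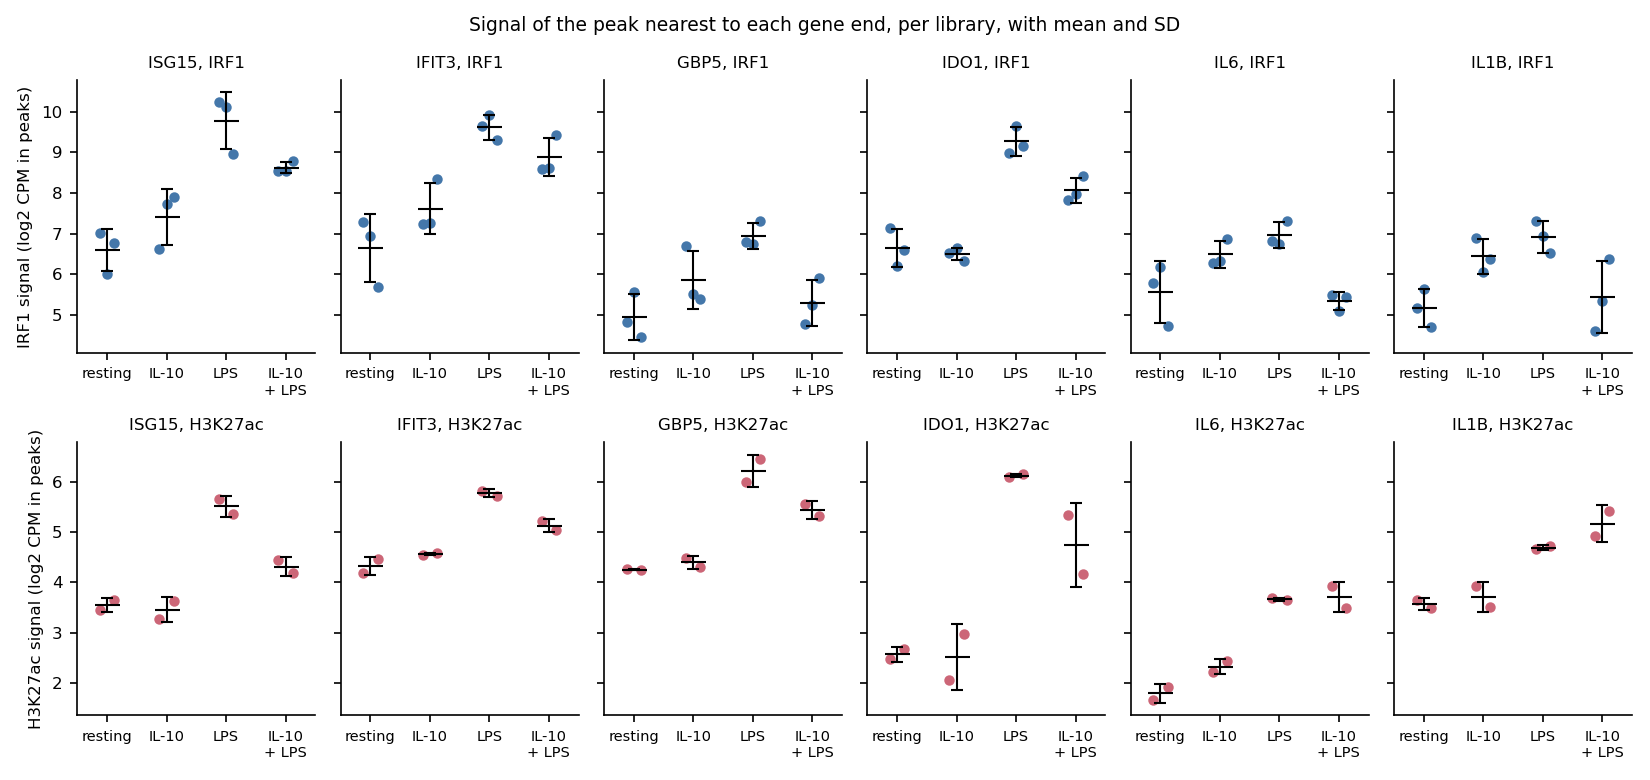
IRF1 signal (top, n = 3) and H3K27ac signal (bottom, n = 2) of the peak nearest to each of 6 genes, in log2 CPM of reads in peaks, for resting, IL-10, LPS and IL-10 + LPS, with points for libraries and bars for the mean and SD. Values and SD are those left after the removal of a shift per column number. ISG15 H3K27ac stands at 5.51 ± 0.21 with LPS and 4.31 ± 0.19 with IL-10 + LPS, while IL1B H3K27ac stands at 4.69 and 5.17.

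H3K27ac of LPS-treated cells fell with IL-10 at interferon-stimulated genes. Near MX1, an antiviral GTPase (chromosome 21, 41425485 to 41426860), it went from 5.66 ± 0.02 to 3.65 ± 0.36 (SD, n = 2), a change of -2.02 ± 0.24 (SE, adjusted p = 0.00329). Peaks of the antiviral genes CMPK2, HERC6 and PARP14 changed by -1.95, -1.32 and -1.18, ISG15 by -1.20 ± 0.19 (adjusted p = 0.00957), GBP5 by -0.79 ± 0.17 (adjusted p = 0.0358) and IFIT3 by -0.64 ± 0.15 (adjusted p = 0.0431, and 0.0727 with the replicate block). Near IRF5, a transcription factor of inflammatory macrophages, the mark fell by 1.25 ± 0.17 (chromosome 7, 128933097 to 128935590, adjusted p = 0.00585). IL15 and its receptor gene IL15RA changed by -1.05 and -1.39, BATF2 by -1.38, APOL6 by -0.94, ATF3 by -2.01 ± 0.33, LIPA, a lysosomal lipase gene, by -1.59 ± 0.18, HK2 by -1.03, SLAMF7 by -1.28 and the IL-10 receptor gene IL10RA by -1.25. Rises were called near the chemokine genes CXCL5, a neutrophil attractant, at 2.09 ± 0.24 (adjusted p = 0.00323), CXCL1 at 1.45, CXCL6 at 1.34, and CCL2, a monocyte attractant, at 1.08 ± 0.15 (adjusted p = 0.00574). Others were near PIM1 (1.35), the formyl peptide receptor gene FPR1 (1.37), VSIG4 (1.42), the transcription factor gene MAF (1.41), TREM1 (1.39), CX3CR1 (1.10), S100A8 (1.18) and MAP3K1 (3.17 ± 0.37). Near NOS2, the inducible nitric oxide synthase gene, 1 peak rose by 3.07 ± 0.48 and another fell by 2.97 ± 0.53. IL6 (0.04 ± 0.24), IL1B (0.48 ± 0.20), TNF (-0.22 ± 0.18), NFKBIA (-0.31) and CD40 (-0.34) did not pass, nor did IDO1 (-1.38 ± 0.35, adjusted p = 0.0582, and 0.000346 with the block). The 2 groups did not overlap at any of the 2011 called peaks, so their lack of overlap at named peaks adds no support. Over all 61446 peaks, 28561 had groups that did not overlap. Chance gives this in 1 of 3 splits of independent libraries, and more often after the column-number removal. Without the intensity trend 36 of the 39 H3K27ac calls of named genes in this comparison were lost.

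Type I interferon-stimulated genes lost H3K27ac at 38 of 210 peaks and gained it at 5 (63 and 10 adjusted over the list alone), with 31 of 57 genes lowered, 4 raised and 22 neither (adjusted p = 5.97e-05, lost at adjusted p = 0.764 with an estimated correlation). Interferon-gamma genes fell at 14 of 203 and rose at 2 (33 and 9 adjusted over the list alone, adjusted p = 0.0777, and 0.0253 with the replicate block). Inflammatory cytokines and chemokines rose at 17 of 179 and fell at 3 (34 and 7 adjusted over the list alone, adjusted p = 0.000808, lost at adjusted p = 0.764 with an estimated correlation), and 10 of the 17 lay in a chemokine gene cluster on chromosome 4, without which the list's camera p went from 0.000124 to 0.106. IL-10 and STAT3 response genes rose at 22 of 332 and fell at 8 (36 and 22 adjusted over the list alone, adjusted p = 0.0124, lost at adjusted p = 0.595 with an estimated correlation). Monocyte identity genes rose at 13 of 289 (13, with 1 lowered, adjusted over the list alone, adjusted p = 0.0187), and ribosomal protein genes fell at 2 of 95, both near RPL3 (1 adjusted over the list alone, adjusted p = 0.0021). Both were lost at adjusted p = 0.764 with an estimated correlation. Not past the threshold were NF-kB genes (4 rose and 4 fell of 295, adjusted p = 0.47), co-stimulation genes (7 and 6 of 254, 0.464), glycolysis genes (5 and 3 of 157, 0.47), lysosome genes (6 and 2 of 200, 0.219), T and NK markers (2 of 74 fell, 0.793), B cell markers (2 of 29 rose, 0.499) and platelet, erythroid and neutrophil markers (4 of 42 rose, 0.0976), the last including PPBP (1.87) and PF4 (1.81) of the same cluster. The last 3 had medians and tests of opposite sign. In all, 1209 H3K27ac peaks rose and 802 fell, but 2352 and 2795 with only the groups compared in the fit, 792 and 1112 without IL-10 + LPS replicate 1, and 111 and 142 over H3K4me3 peaks alone. The count of 2011 became 1020 without LPS replicate 1, 893 without LPS replicate 2 and 229 without IL-10 + LPS replicate 2.

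**Figure D3:**
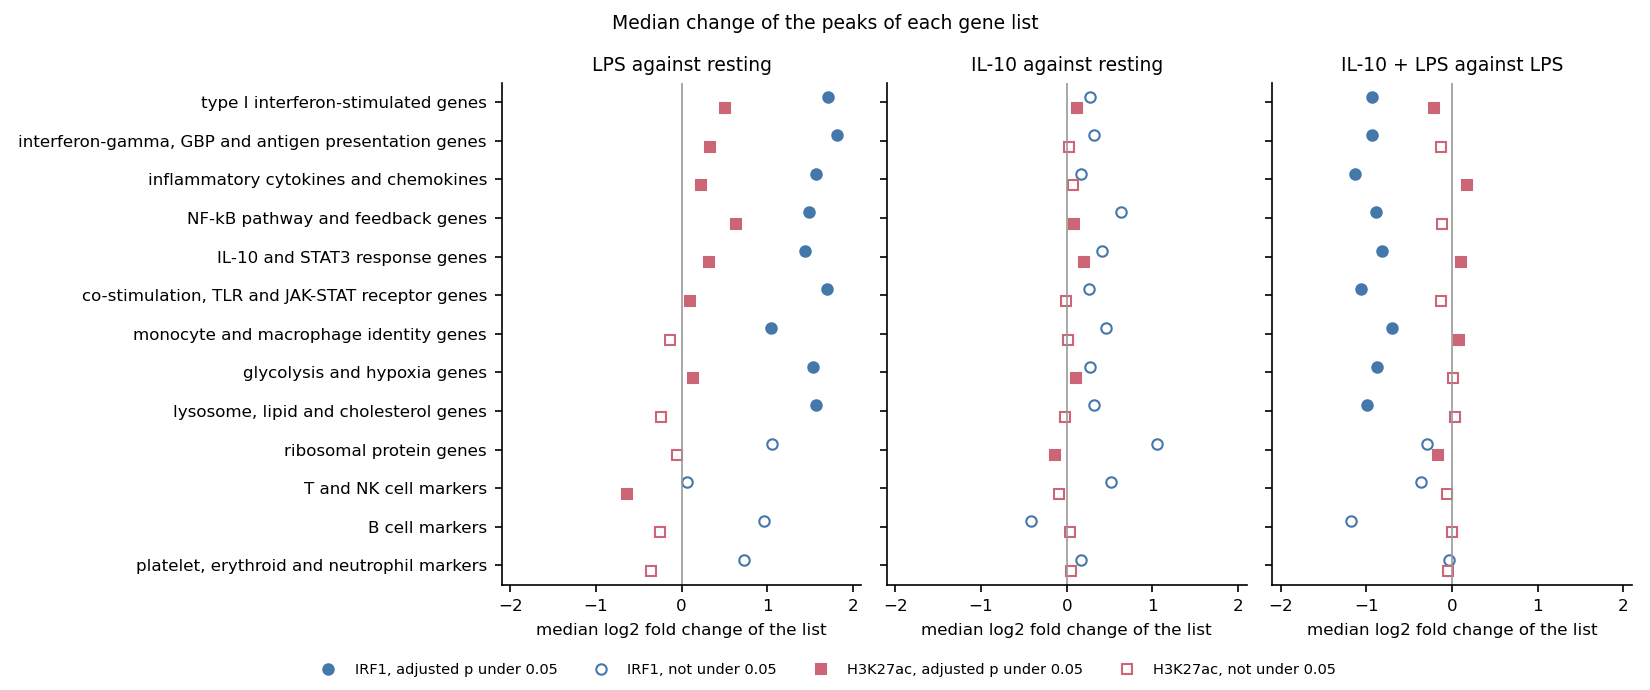
Median log2 fold change of the peaks of each of 13 gene lists for IRF1 (circles) and H3K27ac (squares) in 3 comparisons, filled where the camera adjusted p was under 0.05. For type I interferon-stimulated genes the IRF1 medians are 1.71 with LPS and -0.93 with IL-10 in LPS-treated cells, and the H3K27ac medians 0.51 and -0.21.

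Part of the LPS-raised peaks was called lower with IL-10. Of 2969 IRF1 peaks raised by LPS, 322 (10.8%) were lowered by IL-10, against 116.7 (3.93%) for independent lists. With the replicate block the share was 1.35% (28 of 2067). These shares depend on the power of both comparisons, and that of IL-10 + LPS against LPS was not simulated. By sign alone, 97.2% of the LPS-raised IRF1 peaks were lower with IL-10, by a median of -0.998. Both comparisons share the LPS libraries, and in 20 simulations with no IL-10 effect the share was at most 72.4% and the median -0.35 on average. Of these raised peaks 2815 were marked, and the median IL-10 change of all 7590 marked peaks was -0.81. Simulations and independent lists held no shift shared by marked peaks, so they do not tell LPS-raised peaks from marked peaks at large. The median level of these raised peaks was 4.51 in resting, 5.40 in IL-10, 6.75 in LPS and 5.80 in IL-10 + LPS cells. Of 2375 IRF1 peaks lowered by LPS, a count that was 871 with a common median of the unmarked peaks, 1028 (43.3%) were raised by IL-10 in LPS-treated cells, against 295 for independent lists. By sign 94.2% of them were higher, by a median of 1.55 (at most 76.4% in the simulations, with a mean of 0.49). Of the peaks lowered by LPS 1914 were unmarked, and the median IL-10 change of all unmarked peaks in LPS-treated cells was 0.86. For H3K27ac, 523 of 7087 raised peaks (7.38%) were lowered, against 92.5 (1.31%) for independent lists, and 70.7% were lower by sign, by a median of -0.27 (at most 61.6% in the simulations, with a mean of -0.08). The IRF1 share was 2.46% without LPS replicate 2, and the H3K27ac share 0.572% without IL-10 + LPS replicate 2.

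By median, H3K27ac was lower at peaks that share an IRF1 peak changed by IL-10 in either direction. With IRF1 lowered the median change was -0.18 in 459 peaks against -0.08 in 6241, and 44 of the former were called lower and 7 higher (camera p = 0.011, and p = 0.417 with an estimated correlation). With the IRF1 peaks called by the replicate block the median was -0.40 in 67 peaks against -0.08 in 6633 (camera p = 0.000726 at the preset correlation). With IRF1 raised by IL-10 the median was -0.68 in 155 peaks against -0.08 in 6545 (camera p = 0.00024 at the preset correlation). Of these 155 peaks only 3 were called lower and 2 higher, against 306 and 182 of the 6545. Beyond 2 kb from a gene end the median with IRF1 lowered was -0.16 (p = 0.0848, with the preset correlation). Without LPS replicate 2 the medians were -0.10 and -0.03 (p = 0.0604, with the preset correlation). At H3K27ac peaks sharing an IRF1 peak raised by LPS, the LPS change had a median of 0.54 in 2703 peaks against 0.05 in 3997 (camera p = 2.59e-10, and p = 0.13 with an estimated correlation).

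LPS still changed cells that had IL-10. Against IL-10 alone, IRF1 rose with IL-10 + LPS near IL1RN by 3.18 ± 0.37 (adjusted p = 0.000484), at IL15 by 3.28 ± 0.40, near IDO2 by 2.37 and near GBP5 by 2.49 ± 0.38, while IDO1 gained 1.57 ± 0.35 (adjusted p = 0.0322, and 0.132 with the replicate block). H3K27ac rose near TNC by 4.30, JAK1 by 3.33 and IDO2 by 3.11, and at CCL5 by 2.36, IDO1 by 2.23, IL1B by 1.46, IL6 by 1.39, GBP5 by 1.04 and ISG15 by 0.86 ± 0.19 (adjusted p = 0.015). Interferon-gamma genes gained IRF1 at 6 of 110 peaks, or 2 with the replicate block (13, with 1 lowered, adjusted over the list alone, adjusted p = 3.87e-05, lost at adjusted p = 0.307 with an estimated correlation). IRF1 rose at 1 of 112 peaks of type I interferon-stimulated genes (1 adjusted over the list alone, adjusted p = 0.0304, lost at adjusted p = 0.441 with an estimated correlation). NF-kB genes gained H3K27ac at 90 of 295 and lost it at 12 (109 and 19 adjusted over the list alone, adjusted p = 7.73e-17, lost at adjusted p = 0.0818 with an estimated correlation). Inflammatory genes gained H3K27ac at 45 of 179 and lost it at 1 (50 and 3 adjusted over the list alone, adjusted p = 1.28e-11, lost at adjusted p = 0.172 with an estimated correlation). H3K27ac calls were also made upward for co-stimulation (adjusted p = 8.37e-06), interferon-gamma (3.11e-05), IL-10 and STAT3 response (3.51e-05), type I (0.000235) and glycolysis genes (0.00424), and downward for T and NK markers (0.0206). All were lost, at adjusted p = 0.426, 0.528, 0.0818, 0.54, 0.54 and 0.54 with an estimated correlation. Monocyte identity genes rose at 25 and fell at 22 of 289 (adjusted p = 0.0377, 0.0946 with the replicate block, lost at adjusted p = 0.54 with an estimated correlation), with a median of -0.01 and a mean of -0.05 beside an upward test. For IRF1 144 peaks rose and 161 fell, or 14 and 2 with the replicate block, and with a common median 119 and 199, the median of all peaks going from 0.12 to 0.02. Its count of 305 became 83, 61 and 48 without IL-10 replicates 1, 2 and 3 and 18, 24 and 6 without IL-10 + LPS replicates 1, 2 and 3. For H3K27ac 3663 rose and 3327 fell, or 4765 and 2760 with a common median, which brought the median from -0.19 to -0.02. Its count of 6990 became 3949 without IL-10 replicate 2 and 3444 without IL-10 + LPS replicate 2.

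The IL-10 change of IRF1 signal differed with and without LPS at 2026 peaks, 1186 upward and 840 downward, or 103 and 40 with the replicate block. Near NLRP3 the difference was -5.60 ± 0.89 (adjusted p = 0.0126), where the rise with IL-10 alone was lost at adjusted p = 0.139 with the replicate block. Type I interferon-stimulated genes had 24 of 112 peaks with a more negative change in LPS-treated cells, or 2 with the replicate block (29, with 1 more positive, adjusted over the list alone, camera adjusted p = 6.19e-06). Their median was -1.25, and 8 other lists were called downward as well. Medians of these ran from -1.40 for co-stimulation and -1.39 for NF-kB genes to -1.03 for IL-10 and STAT3 response genes. Of these, lysosome genes were lost at adjusted p = 0.0954 with an estimated correlation. Over all marked IRF1 peaks the median was -1.12, against 0.98 at unmarked ones, and 752 of the 840 downward calls were marked. No random lists of marked peaks were run for the interaction, so the lists are not told apart from marked peaks at large. Quantile normalization gave 915 upward and 406 downward and a common median 1480 and 636, with medians of -0.25 and -0.26 in place of -0.45. The count became 924 and 972 without IL-10 replicates 1 and 3, 912 and 1153 without LPS replicates 2 and 3, and 1050 and 1276 without IL-10 + LPS replicates 2 and 3. For H3K27ac 11 peaks differed, all downward, beside 4947 with an unadjusted p under 0.05, and 163 with the replicate block (11 upward and 152 downward). Type I interferon-stimulated genes had none of 210 past the threshold, or 12 downward with the replicate block (49 downward adjusted over the list alone, camera adjusted p = 1.8e-13, lost at adjusted p = 0.532 with an estimated correlation). Downward calls were also made for interferon-gamma (median -0.22, adjusted p = 0.00242), IL-10 and STAT3 response (-0.19, 0.00242) and NF-kB genes (-0.20, 0.00422), and an upward call for inflammatory genes (0.12, 0.0218). All 4 were lost, at adjusted p = 0.719, 0.339, 0.532 and 0.719 with an estimated correlation. The count of 11 became 75 and 31 without resting replicates 1 and 2, 87 and 53 without IL-10 replicates 1 and 2, 83 without LPS replicate 1, and 78 and 5 without IL-10 + LPS replicates 1 and 2.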

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

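Chosen only after the results were seen were the scaling to unmarked peaks, the splits with the replicate block, the omission of single libraries at peaks shared with IRF1, and the test of H3K27ac at IRF1 peaks raised by IL-10, while the random lists and sets, the omission of the cluster and the quartile were chosen after the patterns but before their own values were seen.

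IRF1 signal rose with LPS at peaks over active marks and fell elsewhere, and IL-10 moved both sets back, so higher signal over background in the LPS libraries could account for part of it. The 10 strongest peaks held 20.0% to 21.8% of the signal in resting, 5.78% to 9.47% in LPS and 14.6% to 16.7% in IL-10 + LPS libraries. At type I interferon-stimulated genes the median LPS change of marked peaks was 1.88. It lay at percentile 100 of 10000 random lists of marked peaks matched on mean value (1.07 to 1.58). Their IL-10 change lay at percentile 0.03, below the range of -0.89 to -0.57. The random peaks were drawn singly, while this list's 112 peaks lie at 52 genes with an estimated correlation of 0.0519. These ranges are therefore too narrow, and those of the IL-10 change were not matched on the LPS change. Whether a shift of background alike at all marked peaks accounts for this list stays open. After libraries were scaled to the unmarked peaks, 9.70% of these were called lower with LPS (713 of 7349) and 685 higher, a balance set by that scaling, so it does not tell a fall from scaling to reads in peaks. Whether IRF1 amounts per cell changed stays open, because no spike-in was used here.

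H3K27ac rose with IL-10 at inflammatory cytokine and chemokine genes of LPS-treated cells, a list with 17 raised and 3 lowered peaks (lost at adjusted p = 0.764 with an estimated correlation). A single cluster on chromosome 4 (73682043 to 74099917), which holds CXCL1, CXCL5, CXCL6, PPBP and PF4, fits as the source, because without its peaks the camera p went from 0.000124 to 0.106. For platelets, erythroid cells or neutrophils in the preparation, the upper quartile of their list outside the cluster was 0.37, under the bar of 1 set for it. That bar lay above the upper quartile of the inflammatory list itself (0.63). Leaving out the cluster also took the marker list from 4 raised peaks of 42 to 1 of 38. This test therefore cannot exclude such cells. It stays open whether the cluster answers IL-10 as 1 unit.

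H3K27ac at peaks that share an IRF1 peak lowered by IL-10 had a median change of -0.18. The set lay at percentile 0.93 of random sets matched on the LPS change (-0.17 to -0.08). Peaks of these sets were drawn singly, which leaves out the correlation between peaks. With that correlation estimated, the camera p of the set went from 0.011 to 0.417. Whether a fall of all LPS-raised peaks accounts for it therefore stays open. The part of single libraries stays open, because without LPS replicate 2 the camera p was 0.0604 at the preset correlation, while the gap stayed similar (-0.10 against -0.03 for other peaks, beside -0.18 against -0.08). Peaks that share an IRF1 peak raised by IL-10 were lower too, by a median of -0.68 over 155 peaks (camera p = 0.00024 at the preset correlation, not run with an estimated one), with 2 called higher and 3 lower. Whether the fall follows the direction of the IRF1 change stays open.

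Splits of 3 against 3 libraries number 10, too few to exclude chance: for LPS against resting 1 of 10 splits called as many as the real 5344 peaks (highest other split 0), for IL-10 against resting 1 of 10 (125, other 0), for IL-10 + LPS against LPS 1 of 10 (2440, other 0) and for IL-10 + LPS against IL-10 1 of 10 (305, other 1). For the interaction 1 of 100 splits drawn reached the real 2026 peaks (highest other split 553, and 422 among splits that part all pairs). With the replicate block 2 of the 100 splits, the real one with 143 peaks included, called as many (highest other split 370, and 28 among the 16 that part all pairs).

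The IL-10 change differed with and without LPS at 2026 IRF1 peaks and 11 H3K27ac peaks, or at 143 and 163 with the replicate block. IRF1 differed near NLRP3 by -5.60, TIAM1 by 6.22 and HOXB3 by -3.70. With the replicate block the calls at ISG15 (-1.97, adjusted p = 0.0305, and 0.0761 with the block), GBP5 (-2.57, 0.0311 and 0.0992), IL6 (-2.54, 0.0231 and 0.0842) and IL1B (-2.76, 0.0232 and 0.0782) were lost. H3K27ac differed near SPEF2 by -2.63, LILRB2 by -2.21, FNIP2 by -2.20, SLC26A11 by -1.84 and SBNO2 by -1.74. These 5 calls held with the replicate block. All 5 were lost with a common median and without the intensity trend, and 4 of them with a pseudocount of 5.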

How the results depend on the processing

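Every group held 2 or 3 libraries, and a lone library left by leave-one-out was assumed to vary like the other groups. Column-number shifts had been removed from the values, so the fit without a block counted too many degrees of freedom. The replicate block lost no called gene list among the 3 main comparisons and moved no total count of peaks by more than 1.5 times other than those printed here. The count-based and motif alternatives were not run. Combinations of quantile normalization with the block, the restriction to marked peaks or to peaks over H3K4me3, and the common median of unmarked peaks were chosen after the data were seen. The cause of each difference was not tested unless stated.

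Called peaks of the named genes kept their call in 3095 of 3467 alternatives and lost it in 372, and called gene lists in 385 of 432 and 47. None changed direction. Losses were most numerous with 1 library left out, among them 51 of 138 IRF1 calls and 32 of 156 H3K27ac calls with IL-10 + LPS against LPS, and 27 of 30 IRF1 calls with IL-10. Also lost were 36 of 39 H3K27ac calls with IL-10 + LPS against LPS without the intensity trend, and 21 of 23 IRF1 calls of that comparison with quantile normalization and the replicate block. The replicate block kept 37 of 39 IRF1 calls of named genes with LPS, 12 of 23 with IL-10 + LPS against LPS, 0 of 5 with IL-10, 4 of 5 with IL-10 + LPS against IL-10 and 3 of 7 for the interaction. For H3K27ac it kept 46 of 46, 38 of 39, 29 of 29, 10 of 11 and 5 of 5 in the same order.

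For IRF1 with LPS against resting, the main count of 5344 became 3556 with quantile normalization, 2097 with quantile normalization and the replicate block, 3450 with marked peaks alone, and 3531 to 4730 with 1 library left out. For IRF1 with IL-10 against resting, 125 became 219 and 573 with pseudocounts of 0.5 and 5, 484 with quantile normalization, 2 with only the groups compared in the fit, 0 with the replicate block, 311 without the intensity trend, 0 with quantile normalization and the replicate block, and 0 to 20 with 1 library left out. For IRF1 with IL-10 + LPS against LPS, 2440 became 1211 with quantile normalization, 853 with the replicate block, 354 with both, 533 with marked peaks alone, 4980 with a common median of unmarked peaks, and 1010 to 1925 with 1 library left out. For IRF1 with IL-10 + LPS against IL-10, 305 became 740 with a pseudocount of 5, 507 with quantile normalization, 16 with the replicate block, 470 without the intensity trend, 7 with quantile normalization and the replicate block, 104 with marked peaks alone, and 6 to 83 with 1 library left out. For the IRF1 interaction, 2026 became 1321 with quantile normalization, 143 with the replicate block, 1299 without the intensity trend, 75 with quantile normalization and the replicate block, 871 with marked peaks alone, and 912 to 1890 with 1 library left out.

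For H3K27ac with LPS against resting, 14561 became 8548 at a change of 1 or more on the log2 scale, 1779 over H3K4me3 peaks alone, and 7943 to 12476 with 1 library left out. For H3K27ac with IL-10 against resting, 1792 became 3269 with quantile normalization, 463 without the intensity trend, 1141 at a change of 1 or more, 195 over H3K4me3 peaks alone, and 1024 to 1449 with 1 library left out. For H3K27ac with IL-10 + LPS against LPS, 2011 became 3191 with quantile normalization, 5147 with only the groups compared in the fit, 90 without the intensity trend, 1122 at a change of 1 or more, 253 over H3K4me3 peaks alone, and 229 to 1904 with 1 library left out. For H3K27ac with IL-10 + LPS against IL-10, 6990 became 4080 at a change of 1 or more, 587 over H3K4me3 peaks alone, and 3444 to 8072 with 1 library left out. For the H3K27ac interaction, 11 became 1 with a pseudocount of 5, 19 without the lowest 25% of peaks, 46 with quantile normalization, 0 with a common median, 163 with the replicate block, 0 without the intensity trend, 133 with quantile normalization and the replicate block, 28 over H3K4me3 peaks alone, and 5 to 87 with 1 library left out.

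The share of LPS-raised IRF1 peaks lowered by IL-10, 10.8% as first computed, was 3.14% with quantile normalization, 1.35% with the replicate block, and 2.46% to 12.5% with 1 library left out. For H3K27ac this share was 0.572% to 12.1% with 1 library left out. The median change of H3K27ac at peaks sharing an IRF1 peak lowered by IL-10 stayed -0.18 with an estimated correlation, while its p rose to 0.417, and was -0.16 beyond 2 kb from a gene end (p = 0.0848) and -0.27 to -0.10 with 1 library left out.

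Gene lists called for IRF1 with IL-10 + LPS against LPS numbered 3 in place of 9 with only peaks within 2 kb of a gene end. For H3K27ac with LPS 2 lists in place of 8 passed with an estimated correlation. For H3K27ac with IL-10 1 list in place of 5 passed with an estimated correlation, 2 within 2 kb, and 3 to 5 with 1 library left out. For H3K27ac with IL-10 + LPS against LPS 0 in place of 5 passed with an estimated correlation. For IRF1 with IL-10 against resting 0 to 1 passed with 1 library left out. With only the wider 50% of the peaks of each list, H3K27ac covered 47.3% of IRF1 and 86.0% of H3K4me3 peaks, H3K4me3 covered 12.4% of IRF1 and 20.3% of H3K27ac peaks, and IRF1 covered 10.6% of H3K27ac and 11.7% of H3K4me3 peaks. With an overlap of 50% of the shorter peak, H3K27ac covered 93.3% of H3K4me3 peaks.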

Other observations

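The test of shared H3K27ac responses in this part was chosen only after its result was seen.

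A part of the H3K27ac peaks raised by IL-10 was shared by resting and LPS-treated cells. Near CD47, an inhibitor of phagocytosis, the mark rose by 2.92 ± 0.24 without and 2.42 ± 0.24 with LPS, near PIM1 by 2.21 and 1.35, and near CXCL1 by 1.74 and 1.45 (n = 2 per group). Near CTSL, a lysosomal protease gene, the rises were 1.22 and 0.78, and a peak of PPARG rose by 1.11 and 1.09. At RPL3 it fell by 1.70 and 1.13. Of 1263 peaks raised by IL-10 alone and 1209 raised in LPS-treated cells, 423 were the same, and 112 were lowered in both settings, against 24.8 and 6.90 for independent lists, and 3 changed in opposite directions. For raised peaks this was 17.0 times the number of independent lists, and the reason for the overlap was not tested.

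LPS and IL-10 also raised the same H3K27ac peaks when given apart, at 649 sites against 146 for independent lists. Near LILRB2, an inhibitory receptor gene, LPS raised the mark by 3.10 ± 0.17 and IL-10 by 2.73 ± 0.17, near CD48 by 2.81 and 1.90, near IL7R by 2.49 and 1.70, near TNIP3 by 2.64 and 2.15, and near CD274 by 2.63 and 1.70. These 2 comparisons share the resting libraries, which adds to the overlap: over all peaks the covariance of the 2 changes was 0.102, against 0.0756 in simulations with neither effect. Near SBNO2 the level was 3.35 in resting, 5.51 in IL-10, 5.18 in LPS and 5.61 in IL-10 + LPS cells.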
